A study of Mus musculus with 12 samples.

How the data were processed

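Gene expression was measured by RNA sequencing in 12 libraries of sorted GFP-positive mouse heart cells, 3 libraries each of days 0, 3, 7 and 30. The processing notes of the authors name cutadapt 1.3, RSEM 1.2.20, edgeR 3.14.0 and the genome build GRCm38. The deposited table holds 14460 genes with an Ensembl identifier and a symbol. Its first 12 value columns are a linear normalised read count, called signal here. Judged from the values, it is the reads of a gene divided by the library total times a TMM factor and multiplied to a common scale. Its other 12 columns are deposited log2 values, the log2 of the same signal with values below 1 set to 0. In all 173520 of 173520 cells the log2 value equalled this within 1e-09.

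Every library's signal was a whole multiple of 1 step, so reads were recovered by division: 100% of the values were whole reads within 0.02 reads. TMM factors computed from the recovered reads differed from the factors worked out from the deposited values by at most 4.16e-09. Depth was 5828904 to 13199576 reads per library. A count of 0 allows up to 3 reads, a signal of 0.190 to 0.543 by library; such floors cover counting error only. The column totals of the signal ran from 823829 to 1260365. Identifiers were looked up in GENCODE M21 (GRCm38), which held 14232 of them (98.4%). Symbols follow the deposited table, with 15 symbols that had been turned into dates restored by identifier; 63 genes had no symbol and 42 symbols stood on a second identifier.

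Genes with a mean signal of at least 1 over the 12 libraries were tested (12879). Log2(signal + 1) was fitted with limma (trend in the variance prior, 4 group means, no pairing of libraries, 8 residual degrees of freedom) and p was adjusted by Benjamini and Hochberg within each comparison, with 0.05 as threshold. Tests were two-sided. The comparisons were day 3, day 7 and day 30 against day 0, day 7 against day 3 and day 30 against day 7, and an F test over the 4 groups. Replicate numbers were checked for pairing: deviations from the group mean of libraries with the same number correlated at a median r of 0.00490 across genes in 18 pairs (-0.0831 to 0.210), and those with different numbers at -0.00690 in 36 pairs, so no pairing was used.

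Before the data were examined, 36 gene lists were fixed (22 of processes, 11 of cell types, 3 of quality; 691 entries, 662 found). They were Ly6C-high monocyte genes, resident cardiac macrophage genes, MHC class II presentation, pro-inflammatory cytokines and chemokines, interferon-stimulated genes, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, the tricarboxylic acid cycle, matrix remodelling, alternative activation, efferocytosis and scavenger receptors, lipid handling, cholesterol synthesis, iron and heme, complement, growth factors, myeloid transcription factors, mRNA stability proteins, microRNA processing, splicing factors, and NADPH oxidase and antimicrobial genes. The others were markers of cardiomyocytes, fibroblasts, endothelium, mural cells, neutrophils, dendritic cells, T and NK cells, B cells, erythroid cells, mast cells and Ly6C-low patrolling monocytes, and early response, mitochondrially encoded and ribosomal protein genes. Lists with at least 3 tested genes were compared with all other genes by camera in limma with a preset correlation of 0.01, and again with an estimated correlation; fry asked whether the genes of a list moved, on balance, 1 way.

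Named genes followed a rule fixed at the same time. In each comparison they were the 6 largest rises and 6 largest falls among genes that passed, with non-overlapping groups, a mean signal of at least 10 and a symbol that is not a clone name; up to 4 members of each list that passed, by size of change; and always Cx3cr1, Ly6c1, Ly6c2, Ccr2, Adgre1 (Emr1 in the table), Itgam, Cd68 and Csf1r. For the 4-group test they were the 3 smallest p in each class of highest group. A part of the genes so named is printed. 1 result of the 4-group test is not reported here.

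Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean of at least 5, quantile normalisation, median centring, a replicate block, a robust prior, array weights, a fit of the compared groups alone, a change of at least 2-fold, both other list tests, and leaving out each library. Added after the data were seen were DESeq2 and the edgeR quasi-likelihood test on recovered reads (the edgeR test had been planned for a table of counts), the deposited log2 values, leaving out the first day 0 and second day 7 libraries, removing trends on GC content and transcript length from each library with splines, and counting the averaged day 30 libraries as 1 sample. The edgeR test on recovered reads called 5608, 2591, 758, 5986 and 5024 genes in the comparisons in the order above and 8111 over the 4 groups; DESeq2 called 5840, 3083, 1327, 6189 and 5391.

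The test was tried on simulated data with 3 against 3 libraries at the depths here and 200 changed genes per comparison. It recovered 32.8% to 47.8% of 2-fold changes, 80.0% to 87.9% of 4-fold changes and 1.52% to 10.6% of 1.5-fold changes; 3.49% to 9.26% of its calls were false, and 0 of 36 unchanged lists passed in each comparison. The simulated genes varied independently and the lists were drawn at random, so this 0 does not cover lists whose members vary together. Each simulated gene also had the same spread in every group, and few genes changed. The real libraries differed in spread and many more genes were called, so these shares need not hold for the real comparisons, least of all with day 30. The median SE of a log2 fold change in the real data was 0.237. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.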

Results

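RNA was measured by sequencing in GFP-positive cells sorted from hearts of Cx3cr1 GFP/+ mice, in which GFP replaces 1 copy of the chemokine receptor gene Cx3cr1 and marks monocytes and macrophages. The 12 libraries formed 4 groups of 3, which the labels call independent biological replicates: hearts without surgery (day 0) and hearts 3, 7 and 30 days after cryoinjury, a freezing injury of the heart wall. Cells of days 0, 7 and 30 were sorted as Ly6c-low and CX3CR1-high, and those of day 3 as Ly6c-high and CX3CR1-low, so every comparison with day 3 joins time after injury and sorting gate. Depth ran from 5828904 to 13199576 reads per library, recovered from the deposited values. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 with Gm26924 and Lars2 took 25.5% to 49.3% of the reads of a library. Levels are given as signal, mean ± SD with n = 3 per group, and changes as log2 fold change ± SE with n = 3 against 3. The SE rests on the spread pooled over all 12 libraries and not on that of the compared groups alone.

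On the first 2 principal components (48.0% and 25.8% of variance) the groups lay apart. The second day 7 library stood at -90.4 on component 2, away from the other day 7 libraries at -31.3 and -32.3. The day 30 libraries were closely alike: pairs of them correlated across genes at r = 0.990 to 0.993 (genes are not independent replicates), with a chi-square per gene of 2.24 to 2.95, against 6.24 to 107 within the other groups. The values do not show whether these 3 libraries came from separate animals, as labelled, or from 1 pool of RNA. If from a pool they are 1 sample, and the counts of genes below that take them as 3 are too high. Among genes chosen after their values were seen, the predicted gene Gm10800 had 126 to 147 signal in the day 30 libraries and at most 0.944 in the 9 others, Gm26870 52.0 to 54.8 against at most 0.766, and Gm21738 18.2 to 23.6 against at most 0.132. Gm26924 and Lars2 were lower in each day 30 library than in each of the others. No label gives a sequencing batch or date.

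**Figure D1:**
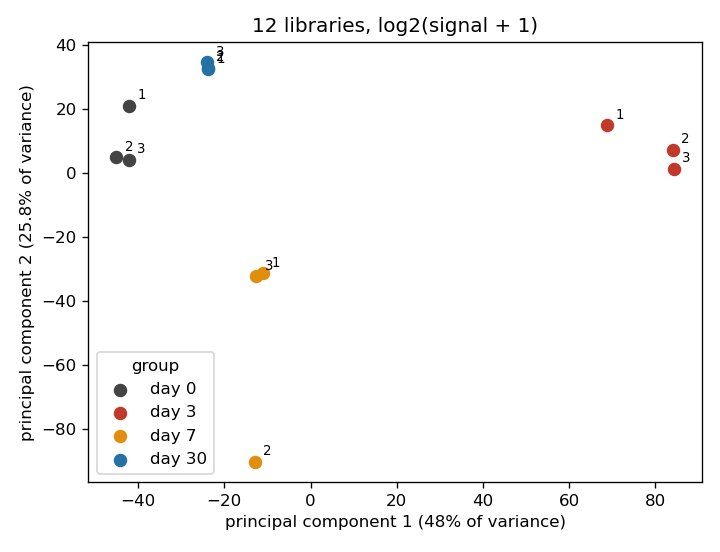
Principal components of the 12 libraries on log2(signal + 1), component 1 on the horizontal axis (48.0% of variance) and component 2 on the vertical axis (25.8%), 1 point per library and 1 colour per group. The second day 7 library lies at -90.4 on component 2.

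The first comparison set Ly6c-high cells of day 3 against Ly6c-low cells of the uninjured heart, and asks how cells of the early injury differ from the macrophages present before it. By camera with a preset correlation, Ly6C-high monocyte, interferon-stimulated and cytokine genes were higher at day 3 and resident macrophage genes lower. These 4 calls ended with an estimated correlation (adjusted p = 0.164, 0.0952, 0.164 and 0.0744). Slfn4, a Schlafen gene of myeloid cells (chromosome 11, 83175186 to 83190216 on GRCm38), rose from 3.71 ± 1.91 to 2547 ± 320.1, a log2 fold change of 9.16 ± 0.24 (adjusted p = 1.7e-12). Thbs1, which encodes the matrix glycoprotein thrombospondin 1, rose by 7.52 ± 0.25 and Vcan, which encodes the proteoglycan versican, by 6.38 ± 0.52. Lyve1, a hyaluronan receptor of resident macrophages (chromosome 7, 110850607 to 110863239), fell from 499 ± 66.6 to 2.08 ± 1.77, a log2 fold change of -7.48 ± 0.36 (adjusted p = 3.9e-10). Cd163, the haptoglobin-hemoglobin scavenger receptor, changed by -6.76 ± 0.34.

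In the list counts that follow, each pair in parentheses gives members higher and lower adjusted over the list alone, followed by the p of camera in limma. Of the 20 Ly6C-high monocyte genes measured at day 3, 18 rose and none fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 4.08 (adjusted p = 1.6e-13, adjusted p = 0.164 with an estimated correlation). Ly6c2, which encodes the surface antigen of the gate, went from 14 ± 11 to 852 ± 205 (6.36 ± 0.74), and Ccr2, the chemokine receptor of recruited monocytes, rose by 2.52 ± 0.23. Interferon-stimulated genes rose in 21 of 22 members (21 and 0 adjusted over the list alone), with a median of 4.53 (adjusted p = 4.35e-22, adjusted p = 0.0952 with an estimated correlation). Rsad2, an antiviral enzyme, reached 6.01 ± 0.23, Ifit2 5.87 ± 0.25 and the chemokine Cxcl10 5.26 ± 0.30. Pro-inflammatory cytokines and chemokines rose in 13 of 17 members (13 and 0 adjusted over the list alone), median 1.84 (adjusted p = 8.45e-07, adjusted p = 0.164 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist held in that list, rose by 4.49 ± 0.23. Arg1, which encodes arginase 1, rose by 6.31 ± 0.31 and Cd300lf, an inhibitory receptor of myeloid cells, by 6.35 ± 0.22.

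Glycolysis and hypoxia genes rose at day 3 in 19 of 22 members and fell in 1 (19 and 1 adjusted over the list alone), median 1.38 (adjusted p = 1.1e-08, adjusted p = 0.164 with an estimated correlation). Vegfa, an angiogenic factor, rose by 5.15 ± 0.35 and Hif1a, the hypoxia-inducible factor, by 2.85 ± 0.15. Matrix remodelling and wound repair genes rose in 19 of 24 and fell in 4 (19 and 4 adjusted over the list alone), median 2.12 (adjusted p = 8.45e-07, adjusted p = 0.157 with an estimated correlation). Spp1, which encodes osteopontin, rose by 6.19 ± 0.34, while the proteases Mmp9, Mmp12 and Mmp13 and the inhibitor Timp2 were the members that fell. Lipid handling genes rose in 13 of 22 and fell in 4 (13 and 5 adjusted over the list alone), median 1.31 (adjusted p = 0.00245, adjusted p = 0.344 with an estimated correlation). Splicing factors rose in 13 of 28 (15 and 0 adjusted over the list alone; adjusted p = 0.00349, adjusted p = 0.496 with an estimated correlation). NADPH oxidase and antimicrobial genes rose in 8 of 17 and fell in 3 (9 and 3 adjusted over the list alone; adjusted p = 0.0261, adjusted p = 0.401 with an estimated correlation).

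Resident cardiac macrophage genes fell at day 3 in 22 of 23 members and rose in none (0 and 22 adjusted over the list alone), median -3.56 (adjusted p = 3.32e-18, adjusted p = 0.0744 with an estimated correlation). Among them were Timd4, a phosphatidylserine receptor (-5.33 ± 0.41), Vsig4, a complement receptor (-5.28 ± 0.26), and Cx3cr1 itself (-1.95 ± 0.15). Outside the list, Slco2b1, an organic anion transporter, changed by -6.34 ± 0.27, Lilra5, an immunoglobulin-like receptor, by -6.27 ± 0.24, Mgl2, a lectin, by -6.25 ± 0.25 and the tetraspanin Cd81 by -5.74 ± 0.17. Cell cycle genes fell in 22 of 30 (0 and 22 adjusted over the list alone), median -1.34 (adjusted p = 9.95e-09, adjusted p = 0.00469 with an estimated correlation), with Top2a, a DNA topoisomerase of dividing cells, at -2.48 ± 0.17. MHC class II presentation genes fell in 8 of 12 and rose in 2 (2 and 9 adjusted over the list alone), median -1.46 (adjusted p = 0.00344, adjusted p = 0.496 with an estimated correlation). H2-Eb1, a class II chain, changed by -3.08 ± 0.21, whereas Ctss and Ifi30, lysosomal processing enzymes, rose. The macrophage marker Emr1 (F4/80) changed by -1.71 ± 0.21, Csf1r by -1.51 ± 0.18, Itgam by 1.39 ± 0.15, Cd68 by 1.32 ± 0.17 and Ly6c1 by 1.85 ± 0.66, each past the test. The Ly6c1 call ended without day 0 replicate 1 (0.78, adjusted p = 0.136) and without day 3 replicates 1, 2 and 3 (adjusted p = 0.0698, 0.0589 and 0.0901).

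Markers of other cell types were compared in the same way. Cardiomyocyte markers fell in 14 of 14 (0 and 14 adjusted over the list alone), with a median of -2.15, or -1.94 with members at 0 reads set to 3 reads per library (adjusted p = 8.45e-07, adjusted p = 0.262 with an estimated correlation). Their summed signal was 259 ± 164 at day 0 and 16.4 ± 3.05 at day 3. The myosin gene Myh6 changed by -4.30 ± 0.49. At day 0 the first library stood apart from the others, with sums of 92 against 265 and 421 for cardiomyocyte, 52.7 against 253 and 172 for T and NK cell and 40.9 against 23.6 and 22.6 for mast cell markers, and 196094 against 425144 and 470693 for mitochondrially encoded genes. T and NK cell markers fell in 10 of 10 (0 and 10 adjusted over the list alone), median -2.37 (adjusted p = 5.6e-05, adjusted p = 0.344 with an estimated correlation). Mast cell markers fell in 5 of 5 (0 and 5 adjusted over the list alone; adjusted p = 0.001, adjusted p = 0.0744 with an estimated correlation), and the proteases Cma1, Cpa3, Mcpt4 and Tpsb2 were listed at 0 in all 3 day 3 libraries, from 8.29 ± 3.75, 6.64 ± 0.889, 6.75 ± 4.01 and 3.98 ± 1.91 at day 0. Neutrophil markers rose in 4 of 7 and fell in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0469, adjusted p = 0.496 with an estimated correlation). With the trends on GC content and transcript length removed, this call ended (adjusted p = 0.0646; median 1.52 with an SD over members of 1.97 before and 1.49 with 1.94 after). The members past the test stayed at 4 higher and 1 lower, so the call ended on a small change of a p near the threshold and not on the fold. Mitochondrially encoded genes fell in 13 of 15 (0 and 13 adjusted over the list alone), median -1.38 (adjusted p = 3.09e-06, adjusted p = 0.414 with an estimated correlation). The first day 0 library, at a sum of 196094, lay within the day 3 range of 181822 to 256208. Ribosomal protein genes fell in 14 of 39 (0 and 13 adjusted over the list alone), median -0.30 (adjusted p = 0.00245, adjusted p = 0.496 with an estimated correlation).

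Of 12879 genes tested by limma, 5698 passed at day 3, 2852 higher and 2846 lower, and 3105 of them changed at least 2-fold. The values of the 2 groups did not overlap in 55.4% of genes, where chance gives 10%. Of the 36 lists 17 passed, 9 up and 8 down, and with an estimated correlation only the cell cycle call held. Splits of these 6 libraries that mixed the groups called up to 18 lists at the preset correlation. Calls of lists that ended without 1 library were neutrophil markers (without day 0 replicate 1, adjusted p = 0.0911, and day 3 replicates 1 and 3, 0.0968 and 0.0539), ribosomal proteins (day 3 replicate 1, 0.0507) and NADPH oxidase genes (day 3 replicate 2, 0.0528).

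The day 7 cells shared the gate of day 0, and this comparison asks what differed in Ly6c-low cells a week after injury. By camera with a preset correlation, lipid handling genes, matrix remodelling genes and fibroblast markers were higher and resident macrophage genes lower. None of these 4 calls held with an estimated correlation (adjusted p = 0.104, 0.116, 0.316 and 0.116). Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 11.4 ± 7.17 to 1011 ± 259, a log2 fold change of 6.54 ± 0.45 (adjusted p = 3.91e-07). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose by 5.48 ± 0.55 (adjusted p = 7.72e-06). Retnla, a secreted product of alternatively activated macrophages, changed by -4.32 ± 0.31 and Lyve1 by -3.84 ± 0.36. Cd5l, a secreted macrophage protein, had 61.7 ± 18.9 at day 7 and 0.181 ± 0.314 at day 0.

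Of the 22 lipid handling genes 16 rose at day 7 and none fell (17 and 0 adjusted over the list alone), median 1.24 (adjusted p = 5.27e-14, adjusted p = 0.104 with an estimated correlation). Trem2, a lipid-sensing receptor, rose by 2.75 ± 0.28 and the fatty acid binding protein gene Fabp5 by 3.41 ± 0.30. Matrix remodelling genes rose in 16 of 24 and fell in 2, Mmp9 and Mmp13 (16 and 2 adjusted over the list alone), median 1.48 (adjusted p = 4.47e-09, adjusted p = 0.116 with an estimated correlation). The summed signal of the matrix list was 5946 in the second day 7 library, 3488 and 3539 in the others and 1618 to 1762 at day 0. Spp1 rose by 4.77 ± 0.34 and the membrane protease gene Mmp14 by 4.10 ± 0.28. Interferon-stimulated genes rose in 15 of 22 and fell in 1, Oas2 (16 and 1 adjusted over the list alone), median 0.92 (adjusted p = 2.02e-08, adjusted p = 0.34 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 of 22 (13 and 0 adjusted over the list alone), median 0.63 (adjusted p = 6.43e-05, adjusted p = 0.374 with an estimated correlation). NADPH oxidase and antimicrobial genes rose in 8 of 17 with 1 lower (8 and 2 adjusted over the list alone; adjusted p = 0.0155, adjusted p = 0.374 with an estimated correlation). Ly6C-high monocyte genes rose in 6 of 20 with 1 lower (6 and 1 adjusted over the list alone), median 0.50 (adjusted p = 0.0243, adjusted p = 0.655 with an estimated correlation). Ccr2 rose by 0.86 ± 0.23, a call that ended without day 0 replicate 1 (0.64, adjusted p = 0.0683) and day 7 replicate 3 (0.57, adjusted p = 0.0534). Ly6c2 did not pass at 0.41 ± 0.74 (adjusted p = 0.725).

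Resident cardiac macrophage genes fell at day 7 in 18 of 23 (0 and 19 adjusted over the list alone), median -1.71, or -1.55 with the member at 0 reads set to 3 reads per library (adjusted p = 5.27e-14, adjusted p = 0.116 with an estimated correlation). Cd163 changed by -3.28 ± 0.34 and Ccl24, an eosinophil-attracting chemokine, by -3.41 ± 0.32. Tppp, a tubulin polymerisation protein gene, changed by -3.51 ± 0.32 and the imprinted gene Peg10 by -3.11 ± 0.26. Cd68, a lysosomal macrophage protein, rose by 1.23 ± 0.17. Cx3cr1 stood at 0.17 ± 0.15 (adjusted p = 0.442), Csf1r at -0.24 ± 0.18 (adjusted p = 0.375), Emr1 at 0.25 ± 0.21 (adjusted p = 0.428), Itgam at 0.16 ± 0.15 (adjusted p = 0.476) and Ly6c1 at 0.05 ± 0.66 (adjusted p = 0.969). Without the first day 0 and the second day 7 library Ly6c1 was -1.48 (adjusted p = 0.00605), over a range of 0.00605 to 0.998 in all alternatives.

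Fibroblast markers rose at day 7 in 12 of 15 and fell in none (14 and 0 adjusted over the list alone), median 2.53 (adjusted p = 2.51e-12, adjusted p = 0.316 with an estimated correlation). Col1a2 rose by 4.89 ± 0.48, Col3a1 by 4.34 ± 0.40 and Postn, which encodes the injury-related matrix protein periostin, by 4.80 ± 0.30. Lox, a collagen cross-linking enzyme gene, was listed at 0 in all 3 day 0 libraries and had 29 ± 15 at day 7. The summed signal of the fibroblast list was 2678 in the second day 7 library and 984 and 688 in the others. Cardiomyocyte markers fell in 5 of 14 (0 and 6 adjusted over the list alone), median -0.71 (adjusted p = 0.00356, adjusted p = 0.485 with an estimated correlation). T and NK cell markers fell in 3 of 10 with 1 higher (1 and 4 adjusted over the list alone; adjusted p = 0.0158, adjusted p = 0.561 with an estimated correlation). The first day 0 library had lower sums than the others of fibroblast (62.3 against 157 and 169), cardiomyocyte (92 against 265 and 421) and T and NK cell markers (52.7 against 253 and 172). Its T and NK sum lay within the day 7 range of 41.8 to 86.9 and its cardiomyocyte sum within 89.9 to 225.

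Ribosomal protein genes rose at day 7 in 14 of 39 (22 and 0 adjusted over the list alone), median 0.43 (adjusted p = 1.15e-05, adjusted p = 0.401 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 34 (1 and 0 adjusted over the list alone), median 0.28 (adjusted p = 0.00387, adjusted p = 0.34 with an estimated correlation). Splicing factors fell in 10 of 28 (1 and 13 adjusted over the list alone), median -0.40 (adjusted p = 0.00108, adjusted p = 0.485 with an estimated correlation). Mitochondrially encoded genes fell in 9 of 15 (0 and 13 adjusted over the list alone), median -0.83 (adjusted p = 1.15e-05, adjusted p = 0.485 with an estimated correlation). Their sum in the first day 0 library, 196094 against 425144 and 470693 in the others, was below that of every day 7 library (222589 to 313484). Early response genes, which cell isolation can induce, fell in 7 of 19 with 1 higher (1 and 10 adjusted over the list alone), median -0.69 (adjusted p = 0.00379, adjusted p = 0.635 with an estimated correlation). Their summed signal was 15809 in the first day 0 library and 5331 and 5693 in the others. Beside these lists, log2 fold changes of day 7 against day 0 correlated across genes with GC content at Spearman rho = 0.388. Removing the trends on GC content and transcript length brought the ribosomal median to 0.26, that of splicing factors to -0.20 and that of oxidative phosphorylation to 0.22. The median of mitochondrially encoded genes went to -0.54, with 5 members lower, and that of NADPH oxidase and antimicrobial genes from 0.52 to 0.32, with 5 higher and 1 lower.

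Limma called 2782 genes at day 7 against day 0, 1466 higher and 1316 lower (1302 and 1552 with median centring), of which 1255 changed at least 2-fold; the groups did not overlap in 32.2% of genes (10% by chance). Of the 36 lists 15 passed, 9 up and 6 down, and none held with an estimated correlation. Splits of the 6 libraries that mixed these groups called up to 21 lists at the preset correlation. With only the 6 libraries of the compared groups in the fit, 1158 genes passed. Calls of lists that ended without 1 library were Ly6C-high monocyte genes (without day 0 replicate 1, adjusted p = 0.338, and day 7 replicate 3, 0.176), early response genes (day 0 replicate 1, 0.394), T and NK cell markers (day 0 replicate 2, 0.0994, and day 7 replicate 2, 0.0926), cardiomyocyte markers (day 0 replicate 3, 0.0563) and NADPH oxidase genes (day 7 replicate 3, 0.0817).

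Day 30 cells, again of the Ly6c-low gate, ask whether the cells a month after injury differ from those before it. By camera with a preset correlation, the lists of cytokines and chemokines and of early response genes were higher, with 12 of 17 and 6 of 19 members past the test. Those of cardiomyocyte and of T and NK cell markers were lower, with 11 of 14 and 3 of 10. None of these 4 calls held with an estimated correlation (adjusted p = 0.0673, 0.409, 0.0742 and 0.235). Chi3l3, a chitinase-like secreted protein gene (chromosome 3, 106147554 to 106167564), rose from 9.39 ± 7.79 to 87.9 ± 4.95, a log2 fold change of 3.71 ± 0.66 (adjusted p = 0.00472). Nr4a3, an orphan nuclear receptor induced early after stimulation, rose by 3.21 ± 0.32 and its relative Nr4a2 by 2.64 ± 0.32. Myh6, the cardiomyocyte myosin, fell from 33 ± 25.3 to 1.18 ± 0.195 (-3.62 ± 0.49, adjusted p = 0.000627). Limma called 796 genes, 444 higher and 352 lower, a count that became 14 (13 higher, 1 lower) when the closely alike day 30 libraries were averaged and counted as 1 sample, as they would be if drawn from 1 pool. In that fit the other groups supply the spread, and the lone sample is assumed to vary like them. Of the 69 genes that the naming rule gave and that passed, 5 then still passed, Bhlhe40, Nr4a3, Ptgs2 and Sfrp2 among them, and 64 did not, Chi3l3, Nr4a2, Il1b, Cxcl1, Myh6, Ttn and Gzma among them. The log2 fold changes of these 69 genes moved by at most 0.0352, with Chi3l3 at 3.72, Nr4a2 at 2.64, Myh6 at -3.61 and Ttn at -2.92, so the calls ended on fewer samples and the spread of the other groups, not on the fold.

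Pro-inflammatory cytokines and chemokines rose at day 30 in 12 of 17 and fell in 1 (14 and 1 adjusted over the list alone), median 1.35 (adjusted p = 1.07e-12, adjusted p = 0.0673 with an estimated correlation). The summed signal of this list was 1656 in the first day 0 library, 577 and 725 in the others and 2890 to 2952 in the day 30 libraries. Whether cell isolation or another library preparation also moved this list was not tested. The neutrophil-attracting chemokine Cxcl1 rose by 2.81 ± 0.64, Ptgs2, the inducible cyclooxygenase, by 2.52 ± 0.24 and the cytokine Il1b by 2.25 ± 0.31. Early response genes rose in 6 of 19 (10 and 0 adjusted over the list alone), median 0.81 (adjusted p = 1.51e-06, adjusted p = 0.409 with an estimated correlation), with Nr4a1 at 2.39 ± 0.43. The first day 0 library had the highest summed signal of this list at day 0, 15809, above every day 30 library (11445 to 11684). The sum was thus higher at day 30 only against the other day 0 libraries, at 5331 and 5693. Interferon-stimulated genes rose in 9 of 22 (10 and 0 adjusted over the list alone), median 0.59 (adjusted p = 3.98e-10, adjusted p = 0.235 with an estimated correlation). Alternative activation genes rose in 3 of 15 with 0 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0182, adjusted p = 0.151 with an estimated correlation), and Il10, an anti-inflammatory cytokine, rose by 2.53 ± 0.31. Growth factors rose in 3 of 21 with 0 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0025, adjusted p = 0.0673 with an estimated correlation). Myeloid transcription factors rose in 4 of 28 with 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.0015, adjusted p = 0.151 with an estimated correlation). Bhlhe40 rose by 2.03 ± 0.17.

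Matrix remodelling genes rose at day 30 in 5 of 24 with 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.000696, adjusted p = 0.241 with an estimated correlation). Fibroblast markers rose in 2 of 15 with 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.0005, adjusted p = 0.431 with an estimated correlation). The first day 0 library had a fibroblast sum of 62.3 against 157 and 169 in the others. Sfrp2, a secreted Wnt antagonist of stromal cells, rose by 3.17 ± 0.33. Ly6C-high monocyte genes rose in 5 of 20 with 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.0203, adjusted p = 0.547 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 18 with 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.00618, adjusted p = 0.284 with an estimated correlation). Resident cardiac macrophage genes fell in 3 of 23 (0 and 10 adjusted over the list alone), median -0.69 (adjusted p = 5.54e-06, adjusted p = 0.238 with an estimated correlation). Lyve1, chosen after its values were seen, stood at -1.05 ± 0.36 (adjusted p = 0.096), and of the sort and model genes Cx3cr1 at -0.22 ± 0.15 (adjusted p = 0.408), Ccr2 at 0.68 ± 0.23 (adjusted p = 0.0946), Ly6c2 at -1.42 ± 0.74 (adjusted p = 0.272), Cd68 at -0.00 ± 0.17 (adjusted p = 0.992) and Emr1 at -0.11 ± 0.21 (adjusted p = 0.8).

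Cardiomyocyte markers fell at day 30 in 11 of 14 (0 and 13 adjusted over the list alone), median -1.93 (adjusted p = 1.21e-14, adjusted p = 0.0742 with an estimated correlation), with the sarcomere gene Ttn at -2.93 ± 0.63. T and NK cell markers fell in 3 of 10 (0 and 9 adjusted over the list alone; adjusted p = 1.99e-06, adjusted p = 0.235 with an estimated correlation), with the granzyme gene Gzma at -2.68 ± 0.59. Mast cell markers fell in 4 of 5 (0 and 4 adjusted over the list alone; adjusted p = 1.94e-06, adjusted p = 0.0302 with an estimated correlation). Endothelial markers passed as a lower list with 0 of 13 members past the test (0 and 0 adjusted over the list alone; adjusted p = 0.00172, adjusted p = 0.444 with an estimated correlation). Mural cell markers fell in 1 of 10 (0 and 3 adjusted over the list alone; adjusted p = 0.0015, adjusted p = 0.416 with an estimated correlation). Erythroid markers did so with 0 of 4 (0 and 0 adjusted over the list alone; adjusted p = 0.029, adjusted p = 0.416 with an estimated correlation). The first day 0 library stood apart from the others in these lists, with sums of 50.7 against 254 and 225 for endothelial, 15.7 against 122 and 139 for erythroid, 47 against 155 and 129.9 for mural, 92 against 265 and 421 for cardiomyocyte, 52.7 against 253 and 172 for T and NK cell and 40.9 against 23.6 and 22.6 for mast cell markers. Its endothelial and erythroid sums were below those of every day 30 library (69.3 to 76.6 and 18.9 to 23.6), so these sums were lower only against the 2 other day 0 libraries. With the GC and length trends removed, the erythroid call ended on a smaller fold (adjusted p = 0.0951; median -1.60 with an SD over members of 0.41 before and -1.30 with 0.44 after).

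Ribosomal protein genes fell at day 30 in 16 of 39 (1 and 25 adjusted over the list alone), median -0.55 (adjusted p = 1.41e-12, adjusted p = 0.151 with an estimated correlation). Oxidative phosphorylation genes fell in 10 of 34 (0 and 16 adjusted over the list alone), median -0.45 (adjusted p = 7.71e-11, adjusted p = 0.0534 with an estimated correlation). Tricarboxylic acid cycle genes had 1 of 17 lower (0 and 3 adjusted over the list alone; adjusted p = 0.0153, adjusted p = 0.368 with an estimated correlation). Splicing factors rose in 2 of 28 with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.00148, adjusted p = 0.416 with an estimated correlation). Mitochondrially encoded genes fell in 2 of 15 with 0 higher (0 and 2 adjusted over the list alone; adjusted p = 6.01e-05, adjusted p = 0.416 with an estimated correlation); the first day 0 library, at a sum of 196094, lay within the day 30 range of 192356 to 200750. The non-coding RNA genes Rn7sk and Rmrp changed by -2.02 ± 0.25 and -1.56 ± 0.31, and Lars2 by -1.71 ± 0.40. Gm26924 and Gm15662 were also lower in each day 30 library (at most 37530 and 1183 signal) than in each other library (at least 53429 and 2207). Whether the make-up of the libraries moved these genes was not tested. Fold changes of day 30 against day 0 correlated across genes with GC content at Spearman rho = -0.376; with GC and length trends removed the ribosomal median was -0.36 and that of oxidative phosphorylation -0.34. The median of splicing factors went from 0.33 to 0.13, that of myeloid transcription factors from 0.32 to 0.20 and that of Ly6C-high monocyte genes from 0.23 to 0.15.

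The groups of days 30 and 0 did not overlap in 40.8% of genes (10% by chance if the 6 libraries vary alike and independently). Libraries as alike as those of day 30 raise this share without any change of a gene, so it cannot show an excess. Of the genes called, 335 changed at least 2-fold. Of the 22 lists that passed (11 up, 11 down) only the mast cell call held with an estimated correlation. The count of 796 was 268 and 402 without day 0 replicate 2 and replicate 3, and 276, 235 and 272 without day 30 replicates 1, 2 and 3. It was 1327 by DESeq2, 3743 with array weights, 2513 without the first day 0 and second day 7 libraries, 2674 in a fit of these 6 libraries alone and 1990 with the second day 7 library left out of the pooled fit. Without 1 library the calls ended of Cxcl1 (adjusted p 0.0644 to 0.0886 without day 0 replicates 2 and 3 and each day 30 replicate), Ttn (0.0501 to 0.07 for the same libraries), Gzma (0.0748 to 0.081 without day 0 replicates 2 and 3 and day 30 replicate 2), Lars2 (0.0637 to 0.102 without day 0 replicate 3 and each day 30 replicate) and Rmrp (0.0516 and 0.0552 without day 0 replicate 3 and day 30 replicate 3). The list calls that ended were Ly6C-high monocyte genes and the tricarboxylic acid cycle (without day 0 replicate 1, adjusted p = 0.721 and 0.103) and endothelial and erythroid markers (without day 0 replicate 2, 0.0749 and 0.131, and replicate 3, 0.0625 and 0.138).

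**Figure D2:**
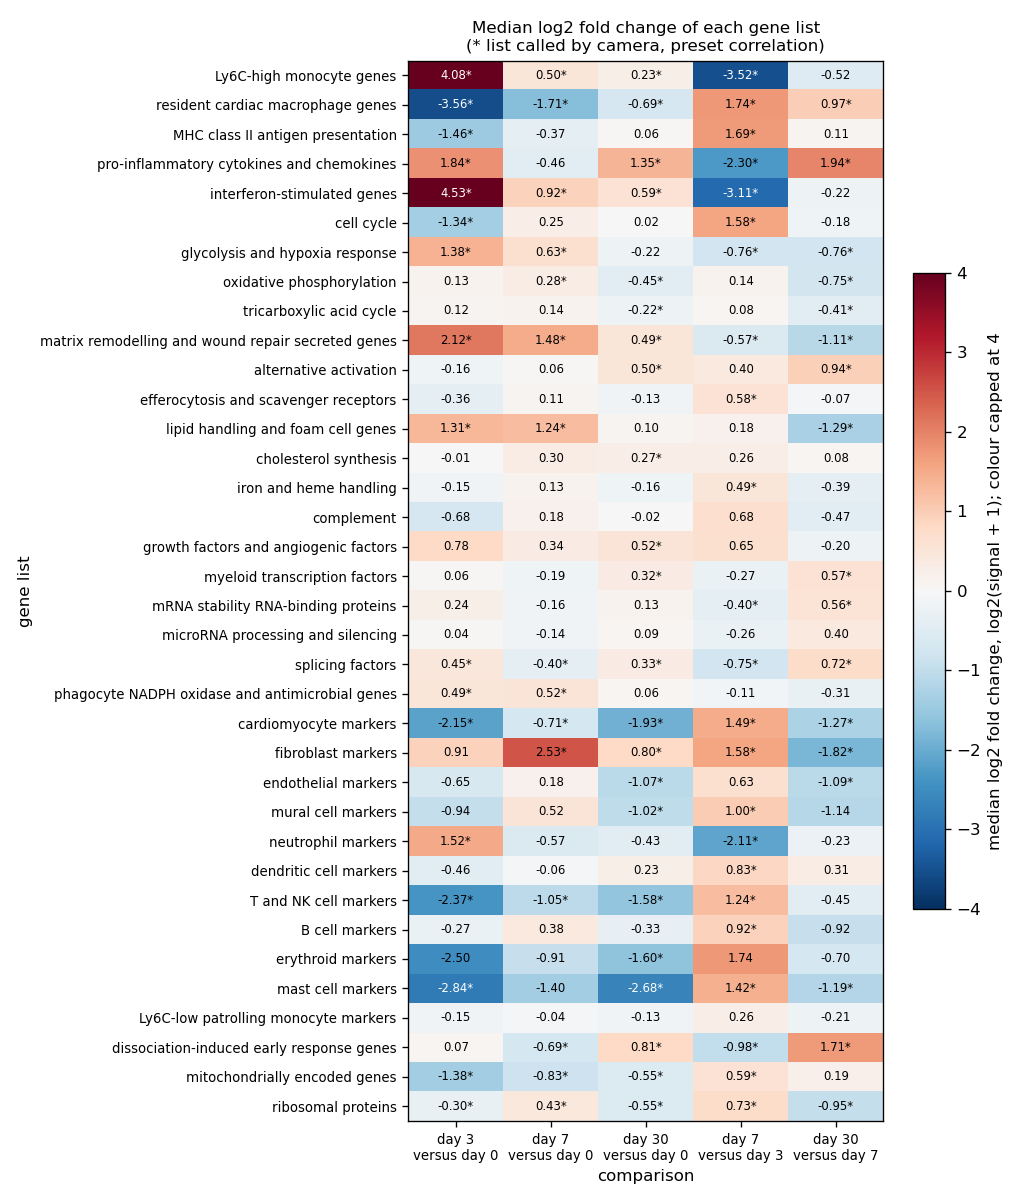
Median log2 fold change of each of the 36 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with colour capped at 4 and * for lists that passed camera with the preset correlation; the mast cell median of -2.84 at day 3 is -2.41 with members at 0 reads set to 3 reads per library. Interferon-stimulated genes had a median of 4.53 at day 3 against day 0 and -3.11 at day 7 against day 3.

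Day 7 against day 3 compares Ly6c-low with Ly6c-high cells of the injured heart, time and gate together. By camera with a preset correlation, Ly6C-high monocyte and interferon-stimulated genes were lower at day 7, and resident macrophage, class II and cell cycle genes higher. With an estimated correlation the cell cycle call held (adjusted p = 0.00172) and the others ended (adjusted p = 0.152, 0.152, 0.152 and 0.373). Slco2b1, the organic anion transporter gene (chromosome 7, 99657804 to 99711340), rose from 3.58 ± 2.72 to 131 ± 10.03 (adjusted p = 4.4e-09). Igf1, a growth factor, rose by 4.34 ± 0.39 and Fcrls, an Fc receptor-like gene of macrophages and microglia, by 4.91 ± 0.34. Ly6c2 fell from 852 ± 205 to 17.3 ± 12.7 (-5.95 ± 0.74) and Slfn4 changed by -6.73 ± 0.24.

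Ly6C-high monocyte genes fell between days 3 and 7 in 19 of 20 (0 and 19 adjusted over the list alone), median -3.52 (adjusted p = 3.65e-13, adjusted p = 0.152 with an estimated correlation). Plac8 changed by -5.64 ± 0.61 and Thbs1 by -5.19 ± 0.25. Interferon-stimulated genes fell in 21 of 22 (0 and 21 adjusted over the list alone), median -3.11 (adjusted p = 1.82e-19, adjusted p = 0.152 with an estimated correlation). Cytokines and chemokines fell in 14 of 17 (0 and 14 adjusted over the list alone), median -2.30 (adjusted p = 1.19e-07, adjusted p = 0.152 with an estimated correlation). Glycolysis and hypoxia genes fell in 14 of 22 and rose in 2, Gpi1 and Pfkfb4 (2 and 15 adjusted over the list alone; adjusted p = 0.000115, adjusted p = 0.373 with an estimated correlation), with Vegfa at -5.08 ± 0.35. The endothelial lipase gene Lipg changed by -5.44 ± 0.26. Matrix remodelling genes fell in 11 of 24 and rose in 4, Mmp2, Mmp12, Timp2 and Sparc (5 and 11 adjusted over the list alone; adjusted p = 0.024, adjusted p = 0.416 with an estimated correlation). The matrix sum was 5946 in the second day 7 library and 3488 and 3539 in the others. RNA-binding proteins of mRNA stability fell in 12 of 25 with 1 higher (1 and 13 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.373 with an estimated correlation). Zfp36, which promotes decay of cytokine mRNAs, changed by -2.18 ± 0.43. Splicing factors fell in 19 of 28 (1 and 20 adjusted over the list alone), median -0.75 (adjusted p = 5.88e-07, adjusted p = 0.313 with an estimated correlation). Early response genes fell in 10 of 19 with 1 higher (1 and 10 adjusted over the list alone; adjusted p = 0.00468, adjusted p = 0.529 with an estimated correlation).

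Cell cycle genes rose between days 3 and 7 in 25 of 30 (26 and 0 adjusted over the list alone), median 1.58 (adjusted p = 2.66e-11, adjusted p = 0.00172 with an estimated correlation). Kif20a, a mitotic kinesin, rose by 2.41 ± 0.28 and Top2a by 2.26 ± 0.17. Resident macrophage genes rose in 16 of 23 (16 and 0 adjusted over the list alone), median 1.74 (adjusted p = 3.08e-09, adjusted p = 0.152 with an estimated correlation). MHC class II presentation genes rose in 9 of 12, with Ctss and Ifi30 lower (9 and 2 adjusted over the list alone; adjusted p = 0.000409, adjusted p = 0.373 with an estimated correlation). H2-Eb1 rose by 2.63 ± 0.21, Cd81 by 4.38 ± 0.17, Lilra5 by 4.34 ± 0.24 and Gpr34, a lysophospholipid receptor gene, by 4.23 ± 0.33. Efferocytosis and scavenger receptor genes rose in 9 of 19 with 1 lower, Msr1 (9 and 1 adjusted over the list alone; adjusted p = 0.0187, adjusted p = 0.152 with an estimated correlation). Iron and heme genes rose in 8 of 16 with 2 lower, Spic and Steap4 (8 and 2 adjusted over the list alone; adjusted p = 0.024, adjusted p = 0.416 with an estimated correlation). The iron exporter gene Slc40a1 rose by 3.06 ± 0.27. Cx3cr1 changed by 2.12 ± 0.15, Ccr2 by -1.67 ± 0.23 and Emr1 by 1.95 ± 0.21.

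Among markers of other cell types, the second day 7 library stood apart from the others with sums of 2678 against 984 and 688 for fibroblast, 225 against 89.9 and 115 for cardiomyocyte and 175 against 72.7 and 57.3 for mural markers. Fibroblast markers rose in 14 of 15 (14 and 0 adjusted over the list alone), median 1.58 (adjusted p = 0.000102, adjusted p = 0.416 with an estimated correlation). Cardiomyocyte markers rose in 10 of 14 (10 and 0 adjusted over the list alone), median 1.49, or 1.38 with members at 0 reads set to 3 reads per library (adjusted p = 0.000415, adjusted p = 0.375 with an estimated correlation). T and NK cell markers rose in 6 of 10 (6 and 0 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.419 with an estimated correlation). B cell markers rose in 2 of 5 (2 and 0 adjusted over the list alone; adjusted p = 0.0467, adjusted p = 0.373 with an estimated correlation). Dendritic cell markers rose in 7 of 13 with 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0491, adjusted p = 0.416 with an estimated correlation). Mast cell markers rose in 4 of 5 (5 and 0 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.152 with an estimated correlation). Mural cell markers rose in 3 of 10 (3 and 0 adjusted over the list alone; adjusted p = 0.0388, adjusted p = 0.529 with an estimated correlation). With GC and length trends removed, the mural call ended on a smaller fold (adjusted p = 0.0686; median 1.0 with an SD over members of 0.50 before and 0.77 with 0.57 after). Neutrophil markers fell in 6 of 7 (0 and 6 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.373 with an estimated correlation). Ribosomal protein genes rose in 31 of 39 (32 and 0 adjusted over the list alone), median 0.73, or 0.64 with those trends removed (adjusted p = 7.77e-09, adjusted p = 0.289 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 15 (7 and 0 adjusted over the list alone; adjusted p = 0.024, adjusted p = 0.567 with an estimated correlation).

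Of the genes tested, 6032 passed in limma between days 7 and 3, 3001 higher and 3031 lower, 3154 of them at least 2-fold, and the groups did not overlap in 50.9% of genes (10% by chance). Of the 36 lists 23 passed, 14 up and 9 down, and only the cell cycle call held with an estimated correlation. Calls of lists that ended without 1 library were mural markers (adjusted p = 0.0648 without day 3 replicate 1 and 0.194 without day 7 replicate 2), dendritic cell markers (0.0731 to 0.127 without day 3 replicate 1 and day 7 replicates 1 and 3) and B cell markers (0.0544 to 0.127 without day 3 replicates 2 and 3 and day 7 replicate 3). The others were matrix remodelling (0.058 and 0.0722 without day 7 replicates 1 and 3), mitochondrially encoded genes (0.058 to 0.0687 without day 3 replicate 1 and day 7 replicates 1 and 3) and iron and heme genes (0.0502 without day 7 replicate 3).

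Day 30 against day 7 follows the Ly6c-low cells from a week to a month after injury. By camera with a preset correlation, lipid handling, ribosomal and matrix remodelling genes and fibroblast markers were lower at day 30, and early response, cytokine and resident macrophage genes higher. None of these 7 calls held with an estimated correlation (adjusted p = 0.138, 0.229, 0.28, 0.405, 0.393, 0.229 and 0.28). Retnla rose from 1.68 ± 1.31 to 29.5 ± 2.21, a log2 fold change of 3.63 ± 0.31 (adjusted p = 6.19e-06), and Nfkbiz, a nuclear regulator of NF-kappaB, by 3.34 ± 0.38. Cd5l fell from 61.7 ± 18.9 to 1.33 ± 0.175 (-4.71 ± 0.51) and Gpnmb changed by -4.41 ± 0.45. Limma called 5103 genes, 2539 higher and 2564 lower (3099 and 2124 with median centring), and 815 when the day 30 libraries were averaged and counted as 1 sample. Of the 71 genes that the naming rule gave and that passed, 51 then still passed and 20 did not, Cxcl1 and Vegfa among them, while the log2 fold changes of the 71 moved by at most 0.0216.

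Lipid handling genes fell between days 7 and 30 in 16 of 22 (0 and 17 adjusted over the list alone), median -1.29 (adjusted p = 6.66e-10, adjusted p = 0.138 with an estimated correlation), and Ctsd, a lysosomal protease gene, changed by -3.45 ± 0.20. Matrix remodelling genes fell in 14 of 24 and rose in 4, Mmp9, Mmp12, Mmp13 and Plau (4 and 16 adjusted over the list alone), median -1.11 (adjusted p = 0.00049, adjusted p = 0.28 with an estimated correlation). The matrix sum was 5946 in the second day 7 library and 3488 and 3539 in the others. Fibroblast markers fell in 11 of 15 (0 and 12 adjusted over the list alone), median -1.82 (adjusted p = 2.37e-06, adjusted p = 0.405 with an estimated correlation). The fibroblast sum was 2678 against 984 and 688 for the second day 7 library and the others. Col1a1 changed by -4.07 ± 0.55, Col1a2 by -3.48 ± 0.48 and Postn by -3.25 ± 0.30. Ribosomal protein genes fell in 32 of 39 (0 and 32 adjusted over the list alone), median -0.95 (adjusted p = 3.85e-12, adjusted p = 0.229 with an estimated correlation). Oxidative phosphorylation genes fell in 26 of 34 (1 and 29 adjusted over the list alone), median -0.75 (adjusted p = 1.33e-09, adjusted p = 0.138 with an estimated correlation). Tricarboxylic acid cycle genes fell in 9 of 17 with 1 higher (2 and 9 adjusted over the list alone; adjusted p = 0.0467, adjusted p = 0.419 with an estimated correlation). Glycolysis and hypoxia genes fell in 11 of 22 with 2 higher (2 and 12 adjusted over the list alone; adjusted p = 0.00201, adjusted p = 0.419 with an estimated correlation). Fold changes of day 30 against day 7 correlated across genes with GC content at Spearman rho = -0.524; with GC and length trends removed the medians were -0.59 for ribosomal proteins and -0.58 for oxidative phosphorylation. That of glycolysis and hypoxia genes went from -0.76 to -0.46, with 1 higher and 10 lower.

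Early response genes rose between days 7 and 30 in 15 of 19 (18 and 0 adjusted over the list alone), median 1.71 (adjusted p = 7.67e-08, adjusted p = 0.393 with an estimated correlation). Cytokines and chemokines rose in 12 of 17 with 1 lower (12 and 2 adjusted over the list alone), median 1.94 (adjusted p = 2.37e-06, adjusted p = 0.229 with an estimated correlation). Cxcl1 rose by 3.31 ± 0.64, Cxcl2 by 3.05 ± 0.58, Nr4a3 by 3.08 ± 0.32 and Nr4a2 by 3.02 ± 0.32. Resident macrophage genes rose in 16 of 23 (16 and 1 adjusted over the list alone), median 0.97, or 0.96 with the member at 0 reads set to 3 reads per library (adjusted p = 4.69e-06, adjusted p = 0.28 with an estimated correlation), with Lyve1 at 2.79 ± 0.36 and Cd163 at 2.44 ± 0.34. Alternative activation genes rose in 9 of 15 with 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.0268, adjusted p = 0.229 with an estimated correlation). Myeloid transcription factors rose in 15 of 28 and fell in 5, Spi1, Cebpa, Irf8, Nr1h3 and Pparg (15 and 5 adjusted over the list alone; adjusted p = 0.0119, adjusted p = 0.271 with an estimated correlation). Their median went from 0.57 to 0.10 with GC and length trends removed (12 higher, 4 lower). Klf2, a factor of quiescence, rose by 2.58 ± 0.25. Splicing factors rose in 17 of 28 (18 and 1 adjusted over the list alone), median 0.72, or 0.36 with GC and length trends removed (adjusted p = 3.07e-05, adjusted p = 0.393 with an estimated correlation). RNA-binding proteins of mRNA stability rose in 14 of 25 with 2 lower (14 and 5 adjusted over the list alone; adjusted p = 0.0301, adjusted p = 0.405 with an estimated correlation). With those trends removed, the call of this list ended on a smaller fold (adjusted p = 0.337; median 0.56 with an SD over members of 0.68 before and 0.11 with 0.71 after), with 6 members higher and 3 lower.

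Cardiomyocyte markers fell between days 7 and 30 in 9 of 14 (0 and 10 adjusted over the list alone), median -1.27 (adjusted p = 0.00133, adjusted p = 0.419 with an estimated correlation). With GC and length trends removed their median was -0.76, with 6 members lower (adjusted p = 0.00864). Mast cell markers fell in 4 of 5 (0 and 5 adjusted over the list alone; adjusted p = 0.0196, adjusted p = 0.229 with an estimated correlation). Endothelial markers fell in 3 of 13 (0 and 0 adjusted over the list alone; adjusted p = 0.0228, adjusted p = 0.676 with an estimated correlation). The second day 7 library stood apart with sums of 255 against 101 and 137 for endothelial and 225 against 89.9 and 115 for cardiomyocyte markers. The endothelial call ended on a smaller fold with GC and length trends removed (adjusted p = 0.0648; median -1.09 with an SD over members of 0.43 before and -0.75 with 0.59 after). Cx3cr1 stood at -0.39 ± 0.15 (adjusted p = 0.0501), Ccr2 at -0.17 ± 0.23 (adjusted p = 0.568), Csf1r at -0.22 ± 0.18 (adjusted p = 0.333) and Cd68 at -1.23 ± 0.17 (adjusted p = 0.000106).

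The groups of days 30 and 7 did not overlap in 55.3% of genes (10% by chance if the libraries vary alike and independently). The closely alike day 30 libraries raise this share too without any change of a gene, so it cannot show an excess. Of the genes called, 2065 changed at least 2-fold. Of the 36 lists 17 passed, 7 up and 10 down, and none held with an estimated correlation. Splits of the libraries that mixed these groups also called up to 17 lists at the preset correlation. Calls of lists that ended without 1 library were alternative activation (adjusted p = 0.0501 without day 7 replicate 1), endothelial markers (0.146 without day 7 replicate 2) and the tricarboxylic acid cycle (0.0521 to 0.125 without day 7 replicate 3 and day 30 replicates 1 and 3); the last was at 0.0537 with the day 30 libraries averaged. Complement, Ly6C-low patrolling monocyte and microRNA processing genes passed in none of the 5 comparisons: their smallest adjusted p were 0.0743, 0.506 and 0.0761. No list that passed differed in sign between its median, its mean and its test.

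Over the 4 groups together, 8232 of 12879 genes passed the limma F test: 2937 were highest at day 3, 2261 at day 7, 1589 at day 30 and 1445 at day 0. Slfn4, Oas3 and Thbs1 had the smallest p among those highest at day 3, with 2547, 827 and 2606 there. Pltp, a phospholipid transfer protein gene, Scamp5 and Ctsd led at day 7, with 416, 46.4 and 4374. Inpp4b, a lipid phosphatase gene, and the lectin gene Cd33 were among those that led at day 30, with 37.9 and 237. Cd81, the epoxide hydrolase gene Ephx1 and Lilra5 led at day 0, with 935, 83.7 and 147.

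**Figure D3:**
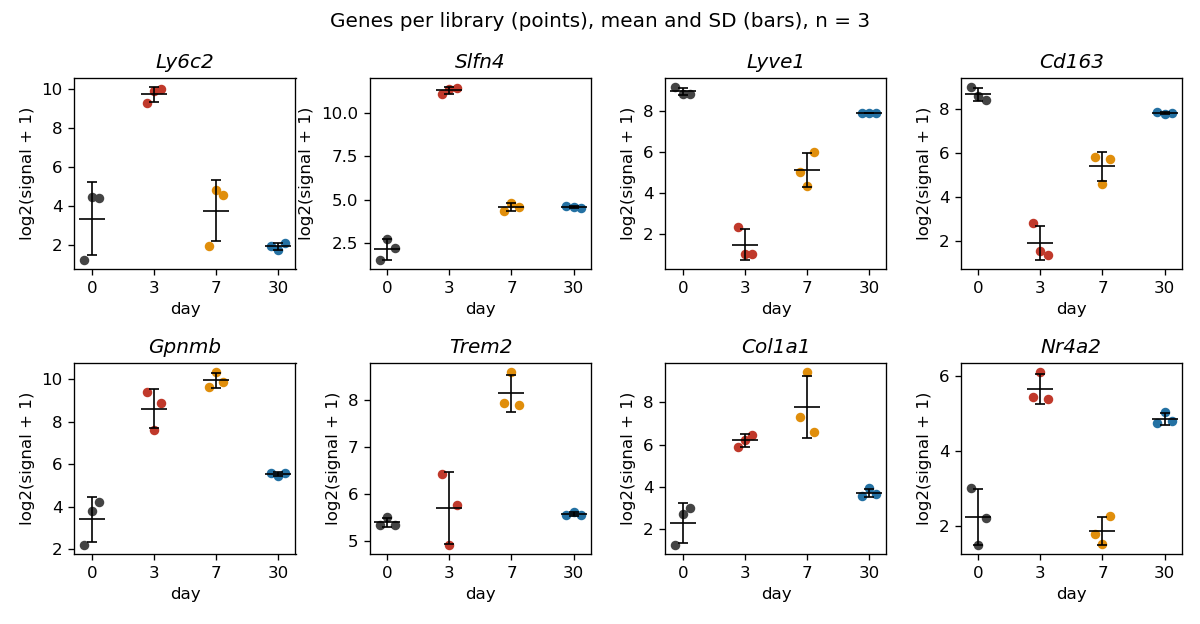
Levels of Ly6c2, Slfn4, Lyve1, Cd163, Gpnmb, Trem2, Col1a1 and Nr4a2 as log2(signal + 1) on the vertical axes against day on the horizontal axes, 1 point per library, bars giving mean and SD (n = 3). Lyve1 had a mean signal of 499 at day 0 and 2.08 at day 3.

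The 3 comparisons with day 0 share its 3 libraries, which cannot be divided between them. Higher in both the day 3 and the day 7 comparison were 799 genes, where independence gives 325, and lower in both 692 (291). For days 3 and 30 the counts were 347 (98.3) and 191 (77.8), and for days 7 and 30 they were 167 (50.5) and 66 (36). Across genes the fold changes correlated at 0.478, 0.466 and 0.176 for these pairs, and in 100 simulations with shared controls and no change at 0.50, 0.50 and 0.499. Their covariances were 0.359, 0.250 and 0.0596, against 0.0367, 0.0366 and 0.0365 simulated, so part of each excess can come from the shared libraries.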

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

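The tests on early response genes at day 30 and on fibroblast markers at day 7, with the bounds used to read them, and the count of cell type lists highest in the second day 7 library were chosen or changed after the results were seen. So were the other scalings of that library's share of lower genes. The other tests on it and the splits of the samples were chosen before.

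Some genes passed in opposite directions against day 0: 179 between days 3 and 7 (97 and 82 by direction), 19 between days 3 and 30 (12 and 7) and 80 between days 7 and 30 (53 and 27). For all of them the difference between the time points was also past the limma test. This adds no support, since opposite changes with the same SE always differ by more than either change. Lists that passed in opposite directions, with the difference past camera, gave the median log2 differences below, none of which held with an estimated correlation. Day 7 minus day 3 was -0.75 for splicing factors and 0.73 for ribosomal proteins. Day 30 minus day 7 was -0.75 for oxidative phosphorylation, 0.72 for splicing factors, 1.71 for early response genes and -0.95 for ribosomal proteins. With GC and length trends removed, day 30 minus day 7 was 0.36 for splicing factors and -0.59 for ribosomal proteins.

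The second day 7 library stood apart from the other day 7 libraries: 1687 of 12879 genes deviated at least 2-fold from their mean, and 50.1% of these were lower (53.0% with median centring, 44.9% with GC and length trends removed). Added RNA of other cells would raise genes, and 25% or more lower had been set beforehand as a value against it. By that bound the share stood against such RNA as the whole cause. Over the 12 libraries the share ran from 33.6% to 76.2%, so no library was under the bound. Whether added RNA would bring a library under it after scaling was not tested, so the share cannot decide. As a part of the cause, for the higher genes, such RNA may be present and cannot be told apart: 8 of 11 cell type lists had their highest day 7 sum there, with fibroblast markers at 2678 against 984 and 688, cardiomyocyte markers at 225 against 89.9 and 115, and endothelial markers at 255 against 101 and 137. Across genes the deviation correlated with GC content at Spearman rho = 0.615, so a GC bias may account for part of it; removing GC and length trends, in an alternative chosen after the result was seen, left 951 such genes among the 12714 with a known GC content. A length bias cannot be told apart (rho = -0.103). The most abundant RNAs of that library differed too, in values looked at after the results were seen. Gm26924 took 23.8% of its reads against 11.4% in each of the other day 7 libraries, and Lars2 5.30% against 2.52% and 2.50%. Lower there were mt-Rnr1 (1.92% against 3.71% and 3.70%) and Malat1 (0.161% against 0.697% and 0.373%). A difference in RNA quality or preparation, or between the animals, was not tested.

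Early response genes were higher at day 30 than at day 0 by camera with a preset correlation (adjusted p = 1.51e-06, 6 of 19 members past the test), a call that ended with an estimated correlation (adjusted p = 0.409). The first day 0 library had the highest level of 14 immediate early genes at day 0, so leaving it out could not lower their median, which went from 1.01 to 1.39, and says nothing of the cause. A response to cell isolation could raise heat shock genes too: their median over 5 genes was -0.13, and 0.60 without that library, with 0 called by limma either way, so it cannot be told apart. Another library preparation at day 30 may be the source and cannot be told apart from the group: Gm10800 had at least 126 signal in each day 30 library and at most 0.944 in each other, while mt-Rnr1, mt-Rnr2, Gm26924 and Lars2 together took up to 25.9% of reads there and 25.5% in the lowest other library. Time after injury, which the design names, remains open and untested against these.

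Fibroblast markers were higher at day 7 than at day 0 by camera with a preset correlation (adjusted p = 2.51e-12), a call that ended with an estimated correlation (adjusted p = 0.316); Col1a1 had 314 and Col3a1 284 signal at day 7. A lower share of macrophages that raised all other cell types alike would leave the fibroblast sum in the same ratio to the others. The log2 ratio of the fibroblast sum to that of cardiomyocyte, endothelial, mural, T and NK and mast cell markers was higher at day 7. Each day 7 library lay above each day 0 library, by at least 2.03, which argues against a rise of all types alike. A lower share in which the other cells were mostly fibroblasts would raise the ratio too, so the ratio cannot tell it apart. List medians were -0.71 for cardiomyocyte markers, a call that ended without day 0 replicate 3 (adjusted p = 0.0563) and with an estimated correlation (adjusted p = 0.485), -1.05 for T and NK cell markers, ended likewise (adjusted p = 0.0994 without day 0 replicate 2, 0.0926 without day 7 replicate 2 and 0.561 with an estimated correlation), -1.40 for mast cell, 0.18 for endothelial and 0.52 for mural markers, the last pair 0.10 and 0.18 with GC and length trends removed. Fibroblast cells or RNA carried into the GFP-positive sort, which should remove such cells, may add to it: 11 fibroblast genes outside the matrix had a median of 1.01 with 4 called. That median was 0.65 without the first day 0 library and 0.60 without the second day 7 library, so it cannot be told apart from collagen expression by the sorted cells.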

How the results depend on the processing

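The alternatives on GC content and length, the libraries in doubt, the deposited log2 values, edgeR and DESeq2 on recovered reads and the averaged day 30 libraries were chosen after the data were seen. Of 513 single results (419 of genes, 94 of lists), 289 kept direction and side of the threshold in every alternative run (286 and 3), and 1 reversed; a change of sign of a value called neither way was not counted. Ly6c1 at day 7 against day 0 was -1.48 without the first day 0 and second day 7 libraries; the cause was not tested. Asking for 2-fold change gave 3105, 1255, 335, 3154 and 2065 genes in the order of the comparisons, by construction fewer. The estimated correlation left 1, 0, 1, 1 and 0 lists (camera in limma), against 17, 15, 22, 23 and 17, and fry, which called 26 at day 3 and 14 at day 30 against day 0, called 17 of the 36 at day 7. For day 30 against day 0 (796) array weights gave 3743, a fit of these groups alone 2674, DESeq2 1327, the second day 7 library left out of the pooled fit 1990, and both libraries in doubt left out 2513. The fold changes stayed the same in the fits that gave 1990 and 2674 (median of all genes -0.00500, as in the main fit). Those counts therefore moved with the estimate of the spread, which the main fit pools over the 4 groups. The cause of the other counts was not tested. Day 7 against day 0 gave 1158 in a fit of these groups alone, also with unchanged fold changes (median -0.0242). The averaged day 30 libraries, by construction fewer samples and a lone sample assumed to vary like the other groups, gave 14 genes against day 0 and 815 against day 7, and 85 of 206 single results lost their call. Leaving out 1 library gave 4646 to 5492, 1867 to 3335, 235 to 955, 5020 to 6049 and 3474 to 5502 genes, 7065 to 8473 over the 4 groups, and 16 to 20, 13 to 17, 20 to 23, 18 to 23 and 16 to 18 lists. Median centring split the calls, higher and lower, into 3042 and 2644, 1302 and 1552, 519 and 278, 2566 and 3419, and 3099 and 2124. The median log2 fold change of all genes at day 30 against day 7 was then 0.102, and 0.0118 without centring. A replicate block, though the numbers show no pairing, gave 5725, 2850, 835, 6040, 5144 and 8230 genes. Depth limits what a count of 0 can show to 3 reads per library.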

Other observations

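Lists with members moving both ways were looked at after the results were seen, as were the per-library values here. Alternative activation genes did not pass as a list at day 3 against day 0 (camera in limma, adjusted p = 0.602, adjusted p = 0.677 with an estimated correlation), with 6 of 15 higher and 7 lower. Arg1 and Chi3l3 had 205 ± 6.24 and 430.4 ± 101 signal at day 3 against 1.95 ± 1.93 and 9.39 ± 7.79 at day 0. The lectin gene Mgl2 and the mannose receptor gene Mrc1 had 3.35 ± 1.61 and 213 ± 85.8 against 317 ± 53.6 and 1943 ± 333. Growth factors divided likewise (adjusted p = 0.868, adjusted p = 0.908 with an estimated correlation), with 11 of 21 higher, Vegfa, Osm and Areg among them, and 7 lower, Igf1 and Pdgfc among them. Igf1 had 309 ± 15.3 at day 0, 23 ± 21.6 at day 3, 383 ± 81.2 at day 7 and 459.6 ± 13.3 at day 30.

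Complement genes rose in 5 of 16 and fell in 8 at day 3 (adjusted p = 0.377, adjusted p = 0.677 with an estimated correlation). C1qa, a chain of the first complement component, had 715 ± 59.7 at day 0 and 95.5 ± 35.7 at day 3, and C3 had 29.3 ± 8.75 and 229.5 ± 79.7. Iron and heme genes rose in 3 of 16 and fell in 7 (adjusted p = 0.133, adjusted p = 0.585 with an estimated correlation); Hmox1, which degrades heme, had 191 ± 89.6 and 516 ± 107, and Slc40a1, the iron exporter, 70.05 ± 11.6 and 7.20 ± 2.77.

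Array weights were 0.142 for the second day 7 library, 0.432 for the first day 0 library and 2.35 to 3.90 for the day 30 libraries. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For genes, 1 of the 10 splits reached the real count in each comparison: the real counts were 5698, 2782, 796, 6032 and 5103, and the highest other 2, 2, 0, 0 and 0. For lists 3, 3, 1, 1 and 2 splits reached the real 17, 15, 22, 23 and 17, with the highest other 18, 21, 21, 17 and 17. Splits that mixed the groups thus called as many lists in 3 comparisons: days 3 and 7 against day 0, and day 30 against day 7. There the count of lists at the preset correlation does not tell the real groups from mixed ones. Of 100 splits of the 12 libraries 1, the real one, reached 8232 genes in the F test, and the highest other was 3195, so the share was under 0.05. These splits take the 12 libraries as independent, which the day 30 libraries are not if they came from 1 pool.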
